A study of Mus musculus with 12 samples.

How the data were processed

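RNA was sequenced from 12 libraries of the caudal region of mouse embryos at embryonic day 10.5, 3 libraries from each of 4 genotypes: wild type, beta-catenin cKO, Emg1 cKO and Vangl2 Lp/Lp. A cKO (conditional knockout) removes a gene only in cells that carry an active recombinase. The recombinase driver, the deleted exons and the strain of the mice are not given in the sources used here. Per the labels, each library held total RNA from a pool of 4 to 7 embryos, extracted with a miRNeasy kit and prepared with a TruSeq Stranded mRNA kit.

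The authors' notes name Trimmomatic 0.39 for read trimming, STAR 2.7.10b for alignment and mm10 as the genome build. The counting tool, its strand setting and the release of the gene annotation are not given in the sources used here. The deposited table held 53342 genes with 2 values per library. The first, in the unit log2, is the log2 of TPM (transcript abundance scaled to a fixed library total) as computed by the authors, with every value of 1 TPM or less set to 0. The second, in the unit expected_counts, is the expected count of reads per gene, with fractions, which the authors made after trimming and alignment and deposited without normalising. Counts divided by TPM followed a single factor per gene and library to within 1.2e-06 on the log2 scale, so TPM under 1 were rebuilt from the counts. All 24 value columns were matched to libraries. The table had 0 genes of the mitochondrial chromosome, so the list of mitochondrially encoded mRNAs was not analysed here. Positions are those of the table, on mm10. GC contents came from GENCODE vM21, which may not be the annotation the authors used.

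The test planned before the data were examined was limma with an intensity trend on log2(TPM + 1), or edgeR on the counts if the table held counts. It did, so the counts were rounded and tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, a joint fit of the 12 libraries with a mean per genotype, and the two-sided quasi-likelihood F test (common dispersion 0.00953, prior degrees of freedom 7.19). Genes with at least 1 TPM in at least 3 of the 12 libraries were tested, which kept 17848 and left out 35494. A gene was called where its Benjamini-Hochberg adjusted p over these genes was under 0.05 within a comparison. Every adjusted p for a gene comes from this fit unless another tool is named. The standard error (SE) of a log2 fold change is its size divided by the square root of F. TPM are given as mean ± SD over 3 libraries. Folds are those of the fit, on TMM-scaled counts, and can differ from the ratio of mean TPM. There were 6 comparisons: each mutant with wild type, and each pair of mutants. The p-values measure spread between pooled libraries, not between embryos.

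Gene lists, 35 in all and 10 of them core, were written from general knowledge before the data were examined. The core lists were WNT/beta-catenin targets, surface ectoderm, epidermal differentiation and periderm, neural plate border and neural crest, neural progenitors, neurons, neuromesodermal and tail bud progenitors, planar cell polarity, small ribosomal subunit biogenesis, and p53 targets. Some genes stand in more than 1 list, such as Grhl3, Tfap2c, Msx1, Lhx1, Wnt3a and Cyp26a1. Each list was tested against all other genes with camera (limma 3.58.1, preset correlation 0.01), and again with an estimated correlation between its genes. Fry tested whether the genes of a list moved, on balance, in a single direction. List p-values were adjusted over the lists of a comparison. Members called were counted over all genes tested and again with p adjusted over the list alone.

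Genes were named by a rule written before the data were examined. It took Ctnnb1, Emg1, Vangl2, Grhl2 and Grhl3, and then the 6 largest called changes in each direction in which all 3 mutant libraries lay beyond all 3 wild-type libraries, leaving out symbols of gene models. It added up to 3 called members of each core list and 1 of each other list with the smallest adjusted p. Between mutants it took the 4 largest per direction, and among genes shared by the 3 mutants up to 6 per direction. Any other gene named was chosen after its values were seen, and the text says so.

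Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The procedure was tested on simulated data of 17848 genes, in which 100 genes changed 1.5-fold and 100 changed 2-fold. The changed genes were drawn only from genes above a floor of expected wild-type reads, so their recovery does not apply to genes with few reads. In the 3 mutant comparisons it recovered 74, 72 and 75 of the former and 95, 94 and 96 of the latter, and called 8, 12 and 18 unchanged genes. Of 6 simulated lists that changed it called 6, and of 3 that did not it called 0, at a camera p under 0.05 before adjustment. The simulated genes varied independently of each other, so this cannot show false list calls that come from correlation between genes. Replicate numbers did not pair libraries: of 18 pairs of libraries with the same number in different groups, 1 had a correlation of residuals above 0.1, and none was as high as the highest of the other pairs, 0.11.

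Alternatives tried were other scalings (median ratio, quantile with limma, library totals alone), log2(TPM + 0.1) and log2(TPM + 1) with limma, no filter and a filter of 5 TPM, no globin genes, a fit of only the 2 groups compared, other estimates of the spread, library weights, a replicate block, DESeq2 1.42.0, a minimum fold of 2, and leaving out each library in turn. The test planned for TPM, limma on log2(TPM + 1), was kept as an alternative once the table was found to hold counts. DESeq2, library totals alone, and the lists and shared genes without each library were added after the data were seen. Leaving a library out was done for the list counts of each mutant against wild type, not for those between mutants.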

Results

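The data were RNA counts from 12 libraries of the caudal region of mouse embryos at E10.5 (embryonic day), with 3 libraries each of wild type, beta-catenin cKO, Emg1 cKO and Vangl2 Lp/Lp embryos. The study asked what goes wrong at the level of transcripts when the neural tube fails to close in these 3 mutants. Its title places Emg1, Grhl3 and beta-catenin in the differentiation of the surface ectoderm. Beta-catenin, encoded by Ctnnb1, carries canonical WNT signals to the nucleus. Emg1 encodes a methyltransferase used in building the small ribosomal subunit. Vangl2 is a core protein of planar cell polarity, and loop-tail (Lp) is a missense allele of it. Grhl2 and Grhl3 encode grainyhead-like transcription factors of the surface ectoderm. Library totals, in the order of replicates, were 34266067, 37314729 and 46464596 reads in wild type, and 32872858, 32863562 and 36768505 in beta-catenin cKO. They were 38247428, 36531484 and 38560969 in Emg1 cKO, and 34845399, 37830848 and 34472685 in Vangl2 Lp/Lp. Between 16143 and 16364 genes lay above 1 TPM in the wild-type libraries, and between 16794 and 17115 in the mutant libraries. Replicates correlated at Pearson's r of 0.986 to 0.991 across genes, which are not independent replicates. The first principal component of the 1000 most variable genes held 24% of the variance and set wild type (-33.6 to -22.9) apart from all mutant libraries (0.28 to 14.7). On the fourth component, with 8.0% of the variance, Vangl2 Lp/Lp replicate 1 lay at -22.0 and replicates 2 and 3 at 17 and 17.6.

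Emg1 mRNA (ENSMUSG00000004268, mm10 chromosome 6, 124704085 to 124712178) fell 1.75-fold in Emg1 cKO, from 73.9 ± 5.7 to 46 ± 2.4 TPM (mean ± SD, n = 3 libraries per group; log2 fold change -0.81 ± 0.08 SE, adjusted p = 9.5e-06). Ctnnb1 mRNA (ENSMUSG00000006932, chromosome 9, 120929216 to 120960507) was not called in beta-catenin cKO, at 823 ± 14 against 811 ± 55 TPM in wild type (-0.09 ± 0.05, adjusted p = 0.20). Its log2 fold change was -0.11 and called with library weights (adjusted p = 0.020), 0.08 with quantile scaling and 0.02 with log2(TPM + 1). A conditional deletion of a few exons in some of the cells need not lower the count of the whole gene, so this value says little about the labels. Vangl2 mRNA (ENSMUSG00000026556, chromosome 1, 172000960 to 172028444) was not called in Vangl2 Lp/Lp, at 77.2 ± 2.0 against 65.0 ± 5.3 TPM (0.17 ± 0.05, adjusted p = 0.074), and rose in Emg1 cKO to 84.9 ± 5.5 TPM (0.27 ± 0.05, adjusted p = 0.0030). Grhl3 (ENSMUSG00000037188, chromosome 4, 135541888 to 135573630) was at 15 ± 1.2 TPM in wild type. It fell to 5.67 ± 2.3 TPM in Emg1 cKO (-1.52 ± 0.22, adjusted p = 0.00023) and to 8.32 ± 0.39 TPM in beta-catenin cKO (-0.96 ± 0.21, adjusted p = 0.0079), and was not called in Vangl2 Lp/Lp at 11.4 ± 1.7 TPM (-0.48 ± 0.21, adjusted p = 0.17). Grhl2 (ENSMUSG00000022286, chromosome 15, 37233036 to 37363569) fell from 3.60 ± 0.93 to 2.04 ± 0.14 TPM in Emg1 cKO (-0.93 ± 0.15, adjusted p = 0.00062). It was not called in beta-catenin cKO (-0.45 ± 0.15, adjusted p = 0.057) or Vangl2 Lp/Lp (-0.32 ± 0.15, adjusted p = 0.20).

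**Figure D1:**
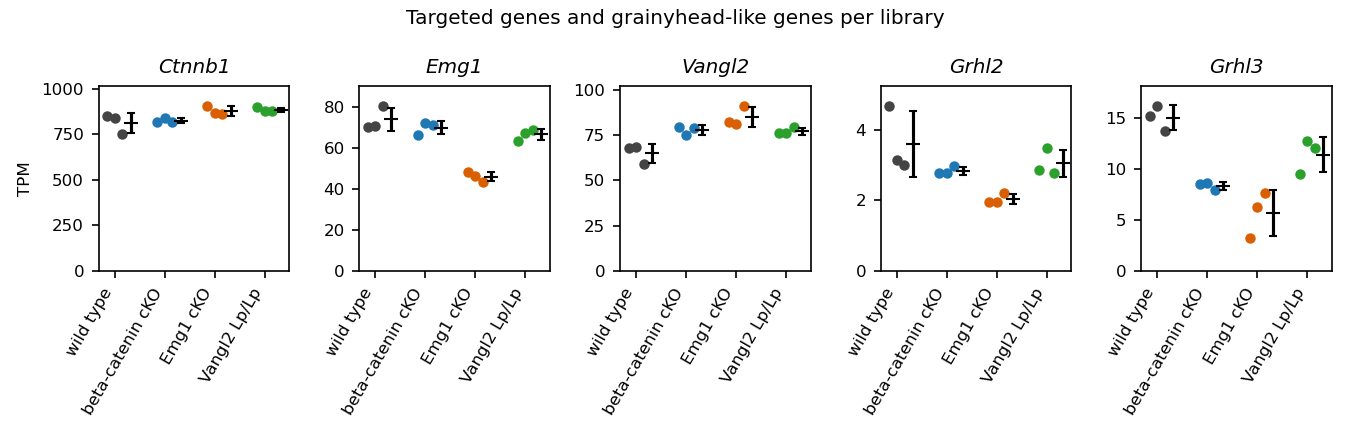
TPM of Ctnnb1, Emg1, Vangl2, Grhl2 and Grhl3 (vertical axes) by genotype (horizontal axes), with 1 point per library and crosses for the mean ± SD of 3 libraries. Emg1 mRNA lay at 46 TPM in Emg1 cKO against 73.9 in wild type, and Grhl3 at 5.67 TPM in Emg1 cKO and 8.32 in beta-catenin cKO against 15.

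The libraries labelled beta-catenin cKO were compared with wild type to ask which genes differ in embryos so labelled. Surface ectoderm genes were lower. Tfap2c fell 3.32-fold, from 13.1 ± 0.19 to 4.27 ± 0.36 TPM (-1.73 ± 0.11, adjusted p = 3.5e-07), Krt5 from 26.8 ± 2.0 to 6.94 ± 1.6 TPM (-2.07 ± 0.17, adjusted p = 3.1e-06), and Wnt6 from 27.9 ± 2.0 to 11.3 ± 0.84 TPM (-1.42 ± 0.11, adjusted p = 2.3e-06). Of 40 surface ectoderm genes tested, 17 were lower and the other 23 were not called, and 20 were lower adjusted over the list alone. The list median was -0.39 (camera adjusted p = 7.9e-17), and the call held with an estimated correlation (adjusted p = 0.040). Of 13 genes of epidermal differentiation and periderm, 2 were lower, Grhl3 and Tgm1, and 4 were lower and 1 higher adjusted over the list alone (median -0.24, camera adjusted p = 0.086). That list passed without beta-catenin cKO replicate 3 (adjusted p = 0.044), and 1 gene was lower without wild type replicate 3 or beta-catenin cKO replicates 1 or 2 and with log2(TPM + 1). With library totals alone 1 was lower and 1 higher. The median was -0.12, -0.40 and -0.38 without wild type replicates 1, 2 and 3. Tgm1 (-0.81 ± 0.26, adjusted p = 0.045) was not called without wild type replicates 2 or 3 or beta-catenin cKO replicates 1 or 2 (adjusted p up to 0.16). WNT/beta-catenin targets were also lower. Tnfrsf19 fell 1.40-fold (-0.49 ± 0.06, adjusted p = 9.8e-05), Tcf7 1.71-fold (-0.77 ± 0.11, adjusted p = 0.00041) and Apcdd1 1.68-fold (-0.75 ± 0.11, adjusted p = 0.00060). Of 25 such targets 12 were lower and 13 not called, with 15 lower and 1 higher adjusted over the list alone (median -0.42, camera adjusted p = 3.5e-09, and adjusted p = 0.14 with an estimated correlation).

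Genes of the neural plate border and neural crest were lower in beta-catenin cKO than in wild type. Sox10 fell 3.62-fold, from 22.9 ± 2.5 to 6.83 ± 1.8 TPM (-1.85 ± 0.15, adjusted p = 3.1e-06), Tfap2b 1.99-fold (-0.99 ± 0.09, adjusted p = 9.8e-06) and Msx1 1.88-fold (-0.91 ± 0.10, adjusted p = 3.5e-05). Of 27 such genes 11 were lower, 2 higher and 14 not called (14 lower and 2 higher adjusted over the list alone, median -0.32, camera adjusted p = 3.5e-09), and the call held with an estimated correlation (adjusted p = 0.047). Tail bud genes went the same way: Fgf8 fell 2.17-fold (-1.12 ± 0.15, adjusted p = 0.00022), Cdx1 2.81-fold (-1.49 ± 0.33, adjusted p = 0.0081) and Cyp26a1 1.58-fold (-0.66 ± 0.15, adjusted p = 0.0087). Cdx1 is also in the list of WNT/beta-catenin targets. Of 24 neuromesodermal and tail bud progenitor genes 6 were lower and 18 not called, and 7 were lower adjusted over the list alone (median -0.28, camera adjusted p = 0.00071, and adjusted p = 0.38 with an estimated correlation). Only 3 were lower without wild type replicates 1 or 2 or any of beta-catenin cKO replicates 1, 2 and 3, with quantile scaling or with log2(TPM + 1).

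Neural genes were higher in beta-catenin cKO. Lhx1 rose 2.56-fold, from 3.97 ± 0.78 to 11.1 ± 0.35 TPM (1.36 ± 0.17, adjusted p = 0.00014), and Ina 2.58-fold (1.37 ± 0.20, adjusted p = 0.00045), while Pou4f1, a gene of dorsal and sensory neurons, fell 2.41-fold (-1.27 ± 0.17, adjusted p = 0.00027). Of 25 neuron genes 16 were higher, 1 lower and 8 not called (17 and 1 adjusted over the list alone, median 0.57, camera adjusted p = 1.2e-10, and adjusted p = 0.19 with an estimated correlation). Among neural progenitor genes Pax6 rose 1.41-fold (0.50 ± 0.07, adjusted p = 0.00020), Ncan 2.59-fold (1.37 ± 0.22, adjusted p = 0.00098) and Dbx2 2.30-fold (1.20 ± 0.21, adjusted p = 0.0015). Of 24, 8 were higher and 16 not called (9 adjusted over the list alone, median 0.30, camera adjusted p = 5.2e-06, and adjusted p = 0.14 with an estimated correlation). Planar cell polarity genes were higher too, Celsr3 by 1.97-fold (0.98 ± 0.16, adjusted p = 0.0010), Ankrd6 by 1.31-fold and Dact1 by 1.27-fold. Of 28, 7 were higher, 1 lower and 20 not called (8 and 2 adjusted over the list alone, median 0.15, camera adjusted p = 0.011, and adjusted p = 0.38 with an estimated correlation). This list was not called without wild type replicate 3 (median 0.093, adjusted p = 0.071), and 4 genes were higher without beta-catenin cKO replicate 3. The 1 lower gene was lost without wild type replicate 1 or beta-catenin cKO replicates 1 or 3 and with log2(TPM + 1), and 2 were lower without wild type replicate 3.

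Small ribosomal subunit biogenesis genes were lower in beta-catenin cKO by small amounts: Wdr36 fell 1.31-fold (-0.39 ± 0.07, adjusted p = 0.0017), Npm1 1.26-fold and Wdr75 1.20-fold. Of 47, 28 were lower and 19 not called (37 lower adjusted over the list alone, median -0.21, camera adjusted p = 7.5e-14, and adjusted p = 0.0996 with an estimated correlation). There were 12 called without beta-catenin cKO replicate 1, 16 without replicate 3, 18 with library totals alone as the scaling, 7 with quantile scaling (median -0.14) and 2 with log2(TPM + 1). Of 30 p53 targets 2 were higher, 2 lower and 26 not called, the same counts adjusted over the list alone. The p53 median was 0.01, or -0.01 with quantile scaling and -0.048 to 0.044 without single libraries, the mean -0.03 and the camera direction lower (adjusted p = 0.72). The called p53 targets were Rps27l (-0.40 ± 0.09, adjusted p = 0.012), Plk3, Pmaip1 and a gene outside the naming rule. There was 1 higher gene without wild type replicates 1 or 2 or beta-catenin cKO replicates 1 or 2, and none without beta-catenin cKO replicate 3. There was 1 lower gene without wild type replicate 3 or beta-catenin cKO replicates 2 or 3. With log2(TPM + 1) 5 were higher and 1 lower, and with quantile scaling 1 and 1. Plk3 (0.39 ± 0.10, adjusted p = 0.017) was not called without wild type replicate 1 or beta-catenin cKO replicate 3 (adjusted p up to 0.067). Pmaip1 (-0.69 ± 0.18, adjusted p = 0.019) was not called without wild type replicate 3 or beta-catenin cKO replicates 2 or 3 (adjusted p up to 0.073).

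In beta-catenin cKO 1335 genes were higher and 1247 lower than in wild type, of which 319 and 158 changed at least 2-fold. The 3 libraries of each genotype did not overlap in 34.7% of genes, against 10% by chance. Large rises were those of Capn11, with 7 reads over the 3 wild-type libraries and 2.04 ± 0.29 TPM in beta-catenin cKO (4.69 ± 0.61, adjusted p = 0.00019), and of Nr1h5, from 1.08 ± 0.84 to 21.1 ± 11 TPM (4.26 ± 0.77, adjusted p = 0.0020). Zfp968 and Zfp969, zinc finger genes of a cluster of paralogs on chromosome 2, rose 10.9-fold and 10.6-fold. Eprn (3.47 ± 0.73, adjusted p = 0.0058) had 5 reads in wild type. Large falls were those of Rps3a3, a copy of a ribosomal protein gene that may share reads with its paralogs (-5.36 ± 0.79, adjusted p = 0.00051), and of Ak8 (-4.25 ± 0.80, adjusted p = 0.0028). Cxcl14 fell from 32.5 ± 2.0 to 6.64 ± 1.1 TPM (-2.41 ± 0.14, adjusted p = 8.6e-08). H2-Eb1 (-2.28 ± 0.53, adjusted p = 0.011) and Tbx3os2, annotated as antisense (-2.49 ± 0.53, adjusted p = 0.0064), fell too, and the strand setting of the counts is not known. Ctse (-2.40 ± 0.69, adjusted p = 0.031) was not called without any of the wild type replicates 1, 2 or 3 or beta-catenin cKO replicates 2 or 3 (adjusted p up to 0.11). The count of 2582 was 1476, 1669 and 1436 without beta-catenin cKO replicates 1, 2 and 3. The share of higher genes among those called depended on the scaling: 51.7% with TMM, 68.8% with library totals alone, and 82.5% with log2(TPM + 1), where the median of all genes shifted by 0.10.

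**Figure D2:**
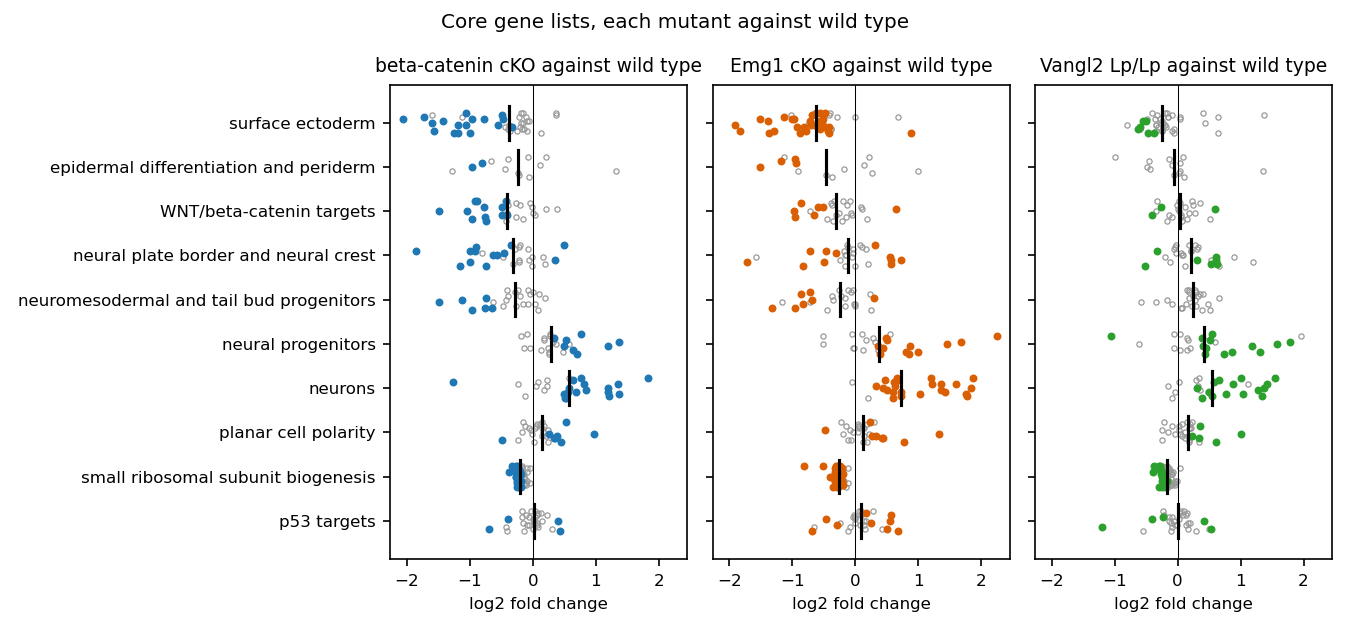
Log2 fold change (horizontal axes) of each tested gene of the 10 core lists (vertical axis) in each mutant against wild type; filled points were called, open points were not, and bars mark medians. Surface ectoderm medians were -0.39, -0.63 and -0.25 and neuron medians 0.57, 0.73 and 0.55 in beta-catenin cKO, Emg1 cKO and Vangl2 Lp/Lp; with other scalings the p53 medians of beta-catenin cKO and Vangl2 Lp/Lp, the border median of Emg1 cKO and the epidermal median of Vangl2 Lp/Lp changed sign.

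Emg1 cKO was compared with wild type to ask what goes with the fall of Emg1 mRNA, and whether surface ectoderm genes differ. They were lower more widely than any other core list except ribosome biogenesis. That order turned with log2(TPM + 1), where 23 of 40 surface ectoderm genes and 10 of 47 ribosome biogenesis genes were lower. Trp63 fell 2.58-fold, from 9.27 ± 1.5 to 3.89 ± 0.37 TPM (-1.37 ± 0.11, adjusted p = 1.5e-06), Wnt6 2.62-fold to 11.6 ± 0.92 TPM (-1.39 ± 0.11, adjusted p = 1.5e-06), and Tfap2c 2.18-fold to 6.52 ± 0.37 TPM (-1.13 ± 0.11, adjusted p = 1.1e-05). Of 40 surface ectoderm genes 29 were lower, 1 higher and 10 not called (31 and 1 adjusted over the list alone). The 1 higher gene was lost with quantile scaling and without wild type replicates 1 or 2 or any Emg1 cKO replicate. The median was -0.63 (camera adjusted p = 1.1e-22), and the call held with an estimated correlation (adjusted p = 0.030). Of 13 genes of epidermal differentiation and periderm 4 were lower and 9 not called, with the same count adjusted over the list alone. Besides Grhl3, Ppl fell 2.26-fold (-1.18 ± 0.22, adjusted p = 0.0017) and Aqp3 1.95-fold (-0.96 ± 0.21, adjusted p = 0.0051). The list median was -0.47 (camera adjusted p = 0.014, and adjusted p = 0.21 with an estimated correlation), or -0.21 without wild type replicate 1, -0.28 without Emg1 cKO replicate 1 and -0.25 with log2(TPM + 1). Among WNT/beta-catenin targets Bambi fell 1.57-fold (-0.65 ± 0.07, adjusted p = 2.9e-05), Tnfrsf19 1.42-fold (-0.51 ± 0.06, adjusted p = 4.2e-05) and Notum 1.97-fold (-0.98 ± 0.17, adjusted p = 0.00082). Of 25 targets 6 were lower, 1 higher and 18 not called, with the same counts adjusted over the list alone (median -0.30, camera adjusted p = 0.00019, and adjusted p = 0.34 with an estimated correlation). The 1 higher became 2 with library totals alone or log2(TPM + 1) and 0 with quantile scaling.

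Neuron genes were higher in Emg1 cKO in nearly the whole list. Dcx rose 3.56-fold, from 9.36 ± 0.48 to 36.3 ± 7.0 TPM (1.83 ± 0.20, adjusted p = 2.8e-05), Ina 3.37-fold (1.75 ± 0.20, adjusted p = 3.9e-05) and Lhx1 3.03-fold (1.60 ± 0.17, adjusted p = 2.6e-05). Of 25 neuron genes 23 were higher and 2 not called, with 23 adjusted over the list alone (median 0.73, camera adjusted p = 1.5e-20, and adjusted p = 0.075 with an estimated correlation). Among neural progenitor genes Nes rose 1.40-fold (0.48 ± 0.06, adjusted p = 9.9e-05), Ncan 3.21-fold (1.68 ± 0.22, adjusted p = 0.00012) and Sox21 1.80-fold (0.85 ± 0.14, adjusted p = 0.00050). Of 24, 12 were higher and 12 not called (14 higher and 2 lower adjusted over the list alone, median 0.38, camera adjusted p = 6.2e-06, and adjusted p = 0.11 with an estimated correlation). Neural plate border and neural crest genes went both ways: Sox9 rose 1.65-fold (0.72 ± 0.08, adjusted p = 3.6e-05), Zic1 rose 1.46-fold and Msx2 fell 1.79-fold (-0.84 ± 0.14, adjusted p = 0.00069). Of 27, 5 were higher, 6 lower and 16 not called, the same counts adjusted over the list alone (median -0.11, or 0.01 with log2(TPM + 1); camera adjusted p = 0.65). The 5 became 3 without Emg1 cKO replicates 2 or 3, and the 6 became 3 without Emg1 cKO replicate 1 or with log2(TPM + 1). Tail bud genes were lower, Cyp26a1 by 2.51-fold (-1.33 ± 0.15, adjusted p = 4.2e-05), Fgf8 by 1.62-fold and Cdx4, also in the list of WNT/beta-catenin targets, by 1.95-fold. Of 24, 6 were lower, 1 higher and 17 not called, the same counts adjusted over the list alone (median -0.24, camera adjusted p = 0.0063, and adjusted p = 0.55 with an estimated correlation). The median was -0.135 and -0.381 without Emg1 cKO replicates 1 and 3. The 1 higher gene was lost without wild type replicate 1 or Emg1 cKO replicate 3, and 2 were higher with log2(TPM + 1).

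Among planar cell polarity genes Celsr3 rose 2.52-fold in Emg1 cKO (1.33 ± 0.16, adjusted p = 5.7e-05), Celsr2 1.71-fold (0.77 ± 0.10, adjusted p = 0.00014) and Dact1 1.36-fold. Of 28, 7 were higher, 1 lower and 20 not called (9 and 1 adjusted over the list alone, median 0.13, camera adjusted p = 0.015, and adjusted p = 0.48 with an estimated correlation). The list was not called without wild type replicate 3 (median 0.072, adjusted p = 0.089) or Emg1 cKO replicate 3 (median 0.080, adjusted p = 0.073). Its 1 lower gene was lost without wild type replicates 1 or 2 or Emg1 cKO replicates 1 or 2, with library totals alone and with log2(TPM + 1). Small ribosomal subunit biogenesis genes were lower. After Emg1 itself, Npm1 fell 1.42-fold (-0.50 ± 0.07, adjusted p = 0.00011) and Tsr1 1.28-fold (-0.36 ± 0.06, adjusted p = 0.00043). Of 47, 42 were lower and 5 not called (44 lower adjusted over the list alone, median -0.26, camera adjusted p = 4.3e-20, and adjusted p = 0.074 with an estimated correlation), and 10 were called lower with log2(TPM + 1). Of 30 p53 targets 6 were higher, 3 lower and 21 not called (7 and 5 adjusted over the list alone, camera adjusted p = 0.44). The median was 0.09, or 0.026 to 0.099 without single libraries and 0.021 with quantile scaling, where 4 were higher and 4 lower. Plk3 rose 1.46-fold (0.55 ± 0.10, adjusted p = 0.0013), Trp53inp1 1.59-fold (0.67 ± 0.12, adjusted p = 0.0013), and Rps27l fell 1.38-fold. The 6 became 3 without wild type replicates 1 or 2 or Emg1 cKO replicate 2, and with log2(TPM + 1) 10 were higher and 1 lower.

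In Emg1 cKO 2021 genes were higher and 1859 lower than in wild type, of which 432 and 121 changed at least 2-fold, and 35.6% of genes had groups that did not overlap. Npy had 2 reads over the wild-type libraries and 63 over Emg1 cKO (adjusted p = 0.0065). Pianp rose from 0.597 ± 0.35 to 7.65 ± 1.9 TPM (3.47 ± 0.44, adjusted p = 9.3e-05), and Zfp968, Zfp969 and Zfp967 of the chromosome 2 cluster rose 11.9-fold, 11.1-fold and 9.82-fold. Cwc22, a splicing gene whose reads may be shared with other copies, fell 11.3-fold from 553 ± 50 to 53.1 ± 19 TPM (-3.50 ± 0.26, adjusted p = 1.4e-06). Slc15a2 fell from 5.54 ± 2.4 to 0.718 ± 0.51 TPM (-3.08 ± 0.55, adjusted p = 0.0012), Spx (-4.14 ± 0.66, adjusted p = 0.00049) to 10 reads over the 3 libraries, and Gpx6 (-3.23 ± 0.67, adjusted p = 0.0033) to 6. Nepn (-2.79 ± 0.64, adjusted p = 0.0063) and Mrap (-2.42 ± 0.53, adjusted p = 0.0044) fell as well. The count of 3880 stayed within 1.5 times when any library was left out (2610 to 3873). Higher genes made up 52.1% of those called with TMM, 68.3% with library totals alone and 82.0% with log2(TPM + 1), where the median of all genes shifted by 0.11.

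Vangl2 Lp/Lp was compared with wild type as the mutant of planar cell polarity. Neural genes were higher. Lhx1 rose 2.68-fold, from 3.97 ± 0.78 to 11.4 ± 2.8 TPM (1.42 ± 0.17, adjusted p = 0.00020), Dcx 2.60-fold (1.38 ± 0.20, adjusted p = 0.00082) and Stmn2 2.53-fold (1.34 ± 0.24, adjusted p = 0.0034). Of 25 neuron genes 15 were higher and 10 not called (17 higher and 1 lower adjusted over the list alone, median 0.55, camera adjusted p = 1.0e-13, and adjusted p = 0.27 with an estimated correlation), and 9 were higher with quantile scaling (median 0.42). Ncan rose 3.45-fold (1.79 ± 0.22, adjusted p = 0.00028), Fabp7 2.49-fold, from 40.0 ± 6.3 to 107 ± 35 TPM (1.31 ± 0.18, adjusted p = 0.00069), and Nes 1.31-fold. Of 24 neural progenitor genes 12 were higher, 1 lower and 11 not called (14 and 2 adjusted over the list alone, median 0.42, camera adjusted p = 1.3e-08, and adjusted p = 0.20 with an estimated correlation), and 2 were lower without Vangl2 Lp/Lp replicate 2. Neural plate border and neural crest genes were higher too: Zic1 rose 1.52-fold (0.61 ± 0.08, adjusted p = 0.00045) and Ednrb 1.54-fold (0.62 ± 0.12, adjusted p = 0.0044). Of 27, 5 were higher, 2 lower and 20 not called (11 and 2 adjusted over the list alone, median 0.20, camera adjusted p = 0.0057, and adjusted p = 0.32 with an estimated correlation), and 3 were higher without Vangl2 Lp/Lp replicate 3 and 8 with library totals alone. There was 1 lower gene without wild type replicates 1 or 3 or Vangl2 Lp/Lp replicate 2 and with library totals alone. None was lower without wild type replicate 2 or Vangl2 Lp/Lp replicates 1 or 3, with quantile scaling or with log2(TPM + 1). Among planar cell polarity genes Celsr3 rose 2.0-fold (adjusted p = 0.0017), Celsr2 1.52-fold and Fzd3 1.28-fold. Of 28, 5 were higher and 23 not called (7 adjusted over the list alone, median 0.16, camera adjusted p = 0.0036, and adjusted p = 0.42 with an estimated correlation). The 5 became 2 without Vangl2 Lp/Lp replicate 1 or with quantile scaling and 3 without wild type replicates 2 or 3 or Vangl2 Lp/Lp replicates 2 or 3, and the median was 0.099 without Vangl2 Lp/Lp replicate 3. Fzd3 (0.35 ± 0.09, adjusted p = 0.030) was not called without wild type replicates 2 or 3 or Vangl2 Lp/Lp replicates 1 or 2 (adjusted p up to 0.12).

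Surface ectoderm genes were lower in Vangl2 Lp/Lp, Krt7 by 1.51-fold (-0.59 ± 0.11, adjusted p = 0.0036), Wnt6 by 1.46-fold (-0.55 ± 0.11, adjusted p = 0.0055) and Krt18 by 1.42-fold (-0.50 ± 0.11, adjusted p = 0.013). Of 40, 6 were lower and 34 not called (11 lower adjusted over the list alone, median -0.25, camera adjusted p = 5.9e-06, and adjusted p = 0.28 with an estimated correlation). Without Vangl2 Lp/Lp replicate 1 the 6 became 2, and Krt18 was not called (adjusted p = 0.059). The 6 became 3 with quantile scaling and 2 with log2(TPM + 1). No gene of epidermal differentiation and periderm was called among 13 (median -0.06, 0.04 with log2(TPM + 1) and -0.19 to 0.016 without single libraries; camera adjusted p = 0.45), and Lor was closest (1.35 ± 0.43, adjusted p = 0.064). Among WNT/beta-catenin targets Bambi fell 1.33-fold (-0.41 ± 0.07, adjusted p = 0.0026). Of 25, 2 were lower, 1 higher and 22 not called, the same counts adjusted over the list alone (median 0.03, or -0.038 to 0.10 without single libraries, mean 0.04, camera direction lower, adjusted p = 0.74). The other calls of that list were Tnfrsf19 (-0.26 ± 0.06, adjusted p = 0.013), lost without wild type replicate 2 or Vangl2 Lp/Lp replicate 1 (adjusted p up to 0.072), and Lgr5. The Lgr5 call (0.59 ± 0.16, adjusted p = 0.035) was lost without wild type replicates 1, 2 or 3 or Vangl2 Lp/Lp replicates 1 or 2 (adjusted p up to 0.099). With quantile scaling no target was higher, and with log2(TPM + 1) none was higher and 1 lower. No tail bud gene was called among 24 (median 0.24, or 0.149 without Vangl2 Lp/Lp replicate 3, camera adjusted p = 0.052), and Dll3 was closest (0.39 ± 0.12, adjusted p = 0.066). That list passed without wild type replicate 2 (adjusted p = 0.036) or Vangl2 Lp/Lp replicate 1 (adjusted p = 1.0e-06). Small ribosomal subunit biogenesis genes were lower, Wdr36 by 1.32-fold (-0.40 ± 0.07, adjusted p = 0.0027), Npm1 by 1.30-fold and Wdr43 by 1.23-fold. Of 47, 16 were lower and 31 not called (29 lower adjusted over the list alone, median -0.17, camera adjusted p = 1.0e-13, and adjusted p = 0.20 with an estimated correlation). The 16 became 6 without Vangl2 Lp/Lp replicate 1, 6 with quantile scaling and 3 with log2(TPM + 1). Of 30 p53 targets 2 were higher, 3 lower and 25 not called, the same counts adjusted over the list alone (mean -0.02, camera direction lower, adjusted p = 0.71), and Fas fell 2.31-fold (-1.21 ± 0.26, adjusted p = 0.011). Rps27l (adjusted p = 0.015) was lost without Vangl2 Lp/Lp replicate 1 (adjusted p = 0.066), as was Plk3 (adjusted p = 0.018), which was also lost without wild type replicate 1 (adjusted p up to 0.086). The 3 lower p53 targets became 1 without Vangl2 Lp/Lp replicate 1. None was higher without wild type replicate 1 or Vangl2 Lp/Lp replicate 1, and 1 was higher without wild type replicate 2 or Vangl2 Lp/Lp replicate 3 or with quantile scaling.

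In Vangl2 Lp/Lp 973 genes were higher and 597 lower than in wild type, of which 265 and 36 changed at least 2-fold, and 28.3% of genes had groups that did not overlap. Rpgrip1 rose 48.6-fold, from 0.376 ± 0.10 to 19.1 ± 6.2 TPM (5.60 ± 0.24, adjusted p = 4.9e-09), and stayed at 0.427 and 0.376 TPM in beta-catenin cKO and Emg1 cKO. Ifi204 rose from 14 reads over the wild-type libraries to 4558 (8.41 ± 1.31, adjusted p = 0.0015), and Ifi207, next to it on chromosome 1, rose 13.3-fold (3.74 ± 0.47, adjusted p = 0.00031). Both lie within 5 Mb of Vangl2, and both were also called higher in beta-catenin cKO (Ifi204 5.97 ± 1.43, adjusted p = 0.012; Ifi207 2.20 ± 0.50, adjusted p = 0.0091). In Emg1 cKO Ifi204 was called (4.98 ± 1.53, adjusted p = 0.030) and Ifi207 was not (adjusted p = 0.0505). These values in the other mutants were looked up after the data were seen and not tried without single libraries. Erbb4 rose 11.5-fold (3.53 ± 0.35, adjusted p = 4.4e-05) and Zfp968 11.4-fold. Rps3a3 fell 38-fold (-5.25 ± 0.78, adjusted p = 0.00097), Ctse from 3.96 ± 0.31 to 0.144 ± 0.23 TPM (-4.89 ± 0.89, adjusted p = 0.0037) and Lyrm7 5.44-fold (-2.44 ± 0.22, adjusted p = 3.0e-05). Several large changes lost their call when a single library was left out. Hbb-bh0 (-2.42 ± 0.56, adjusted p = 0.014) was not called without wild type replicate 3 or Vangl2 Lp/Lp replicate 3 (adjusted p up to 0.059). H2-Bl (adjusted p = 0.020) was not called without wild type replicate 2 or Vangl2 Lp/Lp replicates 1 or 3 (adjusted p up to 0.074), and Snord4a (-1.89 ± 0.53, adjusted p = 0.039) was not called without wild type replicates 1 or 2 or any Vangl2 Lp/Lp replicate (adjusted p up to 0.15). Myl7, a heart muscle gene, was at 220 TPM in Vangl2 Lp/Lp replicate 1 and at 4.50 and 4.00 TPM in replicates 2 and 3. Its call (5.14 ± 1.22, adjusted p = 0.017) was lost without that library or without wild type replicates 2 or 3 (adjusted p up to 0.21). The count of 1570 was 719 without Vangl2 Lp/Lp replicate 1 and 1060 without wild type replicate 3. Higher genes made up 62.0% of those called with TMM, 76.4% with library totals alone and 85.1% with log2(TPM + 1).

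**Figure D3:**
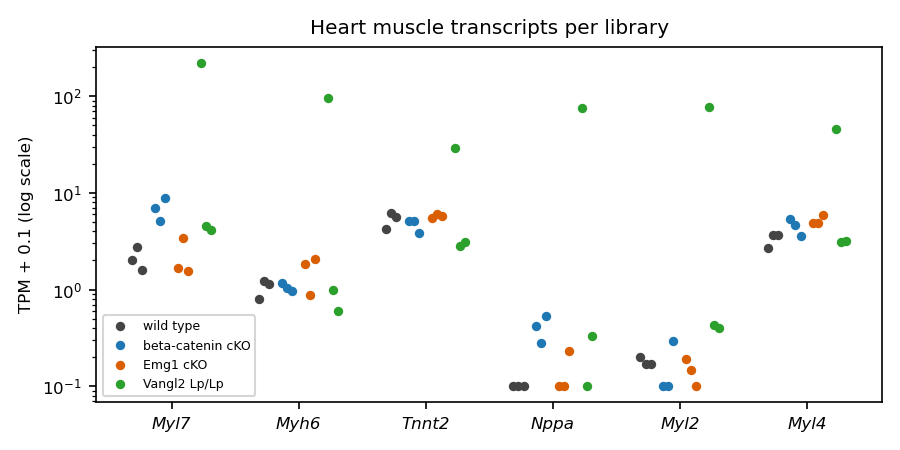
TPM plus 0.1 on a log scale (vertical axis) of heart muscle genes Myl7, Myh6, Tnnt2, Nppa, Myl2 and Myl4 (horizontal axis), with 1 point per library coloured by genotype; the genes shown were chosen after their values were seen. In Vangl2 Lp/Lp replicate 1 Myl7 lay at 220 TPM and Nppa at 76.0 TPM, against at most 8.68 and 0.430 TPM in any other library.

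The mutants were compared with each other to test whether their changes differ. Between beta-catenin cKO and Emg1 cKO 244 genes were higher and 338 lower in beta-catenin cKO, 65 and 96 of them at least 2-fold. Neural plate border and neural crest genes were lower in beta-catenin cKO (10 of 27 called lower, 17 not called; 15 lower and 1 higher adjusted over the list alone, median -0.37, camera adjusted p = 1.3e-12, and adjusted p = 0.073 with an estimated correlation). Surface ectoderm genes were split, with 7 of 40 higher and 4 lower in beta-catenin cKO (median 0.19, camera adjusted p = 0.0012, and adjusted p = 0.40 with an estimated correlation), and WNT/beta-catenin targets did not pass (median -0.10, adjusted p = 0.053). Neuron genes were lower in beta-catenin cKO than in Emg1 cKO (4 of 25; median -0.28, adjusted p = 4.6e-07, and adjusted p = 0.37 with an estimated correlation), and ribosome biogenesis genes slightly higher (2 of 47, or 1 with quantile scaling or log2(TPM + 1); median 0.06, adjusted p = 0.00074, and adjusted p = 0.40 with an estimated correlation). The ribosome biogenesis list includes Emg1, the targeted gene, with 9790 reads over the beta-catenin cKO libraries and 7113 over Emg1 cKO. Its own fall in Emg1 cKO may be among the calls of that list. Capn11 (4.16 ± 0.58, adjusted p = 0.00097) and Nr1h5 (4.48 ± 0.78, adjusted p = 0.0046) were higher in beta-catenin cKO. BC049730 (-6.59 ± 1.13, adjusted p = 0.0042), Padi4 (-3.52 ± 0.55, adjusted p = 0.0023) and Ttll6 (-3.34 ± 0.50, adjusted p = 0.0015) were lower. Spx was not called without beta-catenin cKO replicates 2 or 3 or Emg1 cKO replicate 2 (adjusted p 0.014, up to 0.056). Nepn was not called without beta-catenin cKO replicates 1 or 3 (0.018, up to 0.10). Npy, with 2 and 63 reads, was not called without any beta-catenin cKO replicate or Emg1 cKO replicates 1 or 2 (0.035, up to 0.16). The count of 582 was 341, 343 and 231 without beta-catenin cKO replicates 1, 2 and 3, and 353 and 252 without Emg1 cKO replicates 1 and 2.

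Between beta-catenin cKO and Vangl2 Lp/Lp 289 genes were higher and 401 lower in beta-catenin cKO, 61 and 146 of them at least 2-fold. Neural plate border and neural crest genes were lower in beta-catenin cKO (16 of 27; 21 lower and 1 higher adjusted over the list alone, median -0.64, camera adjusted p = 2.8e-32), and the call held with an estimated correlation (adjusted p = 0.0029). So were WNT/beta-catenin targets (9 of 25, or 5 with log2(TPM + 1); median -0.34, adjusted p = 3.8e-14, and adjusted p = 0.076 with an estimated correlation), surface ectoderm genes (12 of 40; median -0.13, adjusted p = 1.0e-08; adjusted p = 0.13) and tail bud genes (6 of 24; median -0.52, adjusted p = 3.9e-13; adjusted p = 0.14). Rec8 (2.56 ± 0.35, adjusted p = 0.00073) and Capn11 (4.23 ± 0.59, adjusted p = 0.00077) were higher in beta-catenin cKO, and Rpgrip1 (-5.52 ± 0.24, adjusted p = 6.3e-09), Padi4 (-3.56 ± 0.55, adjusted p = 0.0017) and Ttll6 (-3.15 ± 0.50, adjusted p = 0.0019) lower. Guca1b was not called without beta-catenin cKO replicates 1 or 3 or Vangl2 Lp/Lp replicates 2 or 3 (adjusted p 0.027, up to 0.11). Ppp1r3e was not called without any beta-catenin cKO replicate or Vangl2 Lp/Lp replicates 2 or 3 (0.035, up to 0.14), nor Dlx6 without beta-catenin cKO replicates 2 or 3 or Vangl2 Lp/Lp replicate 1 (0.018, up to 0.091). The count of 690 was 441, 401 and 371 without beta-catenin cKO replicates 1, 2 and 3, and 433 without Vangl2 Lp/Lp replicate 2.

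Between Emg1 cKO and Vangl2 Lp/Lp 235 genes were higher and 270 lower in Emg1 cKO, 36 and 61 of them at least 2-fold. Surface ectoderm genes were lower in Emg1 cKO (13 of 40; 24 lower adjusted over the list alone, median -0.35, camera adjusted p = 1.7e-21), and the call held with an estimated correlation (adjusted p = 0.035). Epidermal genes (1 of 13, or 2 with quantile scaling; median -0.40, adjusted p = 0.0031, and adjusted p = 0.19 with an estimated correlation), tail bud genes (6 of 24, or 3 with log2(TPM + 1); median -0.50, adjusted p = 3.1e-12; adjusted p = 0.19) and WNT/beta-catenin targets (4 of 25, or 2 with quantile scaling and 1 with log2(TPM + 1); median -0.25, adjusted p = 6.0e-08; adjusted p = 0.19) were also lower. So were border and crest genes (3 of 27 lower, or 1 with log2(TPM + 1), and 1 higher; median -0.14, adjusted p = 1.8e-05; adjusted p = 0.15) and ribosome biogenesis genes (2 of 47, or 1 with quantile scaling or log2(TPM + 1); median -0.09, adjusted p = 8.8e-07; adjusted p = 0.22). Neuron genes were higher (2 of 25; median 0.23, adjusted p = 2.1e-07; adjusted p = 0.24). Emg1 itself belongs to the ribosome biogenesis list, with 7113 reads over the Emg1 cKO libraries and 9890 over Vangl2 Lp/Lp. Its fall may be among the calls of that list. Siah3 was higher in Emg1 cKO (1.58 ± 0.25, adjusted p = 0.0031), and Rpgrip1 (-5.71 ± 0.24, adjusted p = 2.1e-09) and Nepn (-3.64 ± 0.62, adjusted p = 0.0051) lower. Ctse and H2-K2 were not called without Vangl2 Lp/Lp replicate 2 or Emg1 cKO replicate 1 (adjusted p 0.021 and 0.022, up to 0.090 and 0.096), nor Ccdc60 without these or Emg1 cKO replicate 3 (0.026, up to 0.091). Myl7 and Serpinf2 were not called without Vangl2 Lp/Lp replicate 1 or any Emg1 cKO replicate (0.032 and 0.044, up to 0.21 and 0.26). The count of 505 was 220 and 319 without Vangl2 Lp/Lp replicates 2 and 3, and 277 and 186 without Emg1 cKO replicates 1 and 2.

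The 3 mutants were also compared for the genes they share. In all 3 mutants 568 genes were called higher and 312 lower than in wild type. Among the higher genes, Acsl6 rose from 1.1 ± 0.13 TPM to 3.79 ± 0.32, 4.46 ± 0.31 and 3.81 ± 0.43 TPM in beta-catenin cKO, Emg1 cKO and Vangl2 Lp/Lp, and Cadps from 1.18 ± 0.17 TPM to 3.5 ± 0.10, 4.95 ± 0.25 and 3.02 ± 0.27 TPM, while Apc2 rose as well. Zfp968, Zfp969 and Zfp966 rose from 0.231, 0.295 and 0.421 TPM in wild type to between 2.62 and 3.70 TPM. Among the lower genes, Lyrm7 fell from 6.99 ± 0.86 TPM to 2.57 ± 0.40, 2.02 ± 0.40 and 1.36 ± 0.41 TPM, Slc2a1 from 280 ± 26 TPM to 235 ± 13, 197 ± 3.1 and 217 ± 19 TPM, and Tmco1, Mif, Tfrc and Rps3a2, a ribosomal protein copy, fell as well. Pairs of mutants shared 950 higher and 820 lower genes (beta-catenin cKO and Emg1 cKO), 610 and 356 (beta-catenin cKO and Vangl2 Lp/Lp) and 798 and 429 (Emg1 cKO and Vangl2 Lp/Lp). The same 3 wild-type libraries entered every comparison, which alone makes fold changes correlate across genes: Pearson's r was 0.67, 0.64 and 0.68, against 0.49, 0.48 and 0.49 on average in simulated groups without changes. The 880 shared genes became 557 without wild type replicate 3, 543 and 566 without beta-catenin cKO replicates 1 and 3, and 478 without Vangl2 Lp/Lp replicate 1.

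Lists of other cell types are given for beta-catenin cKO, Emg1 cKO and Vangl2 Lp/Lp in that order. Somite and skeletal muscle genes were higher in beta-catenin cKO (7 of 21; median 0.23, camera adjusted p = 1.8e-06, and adjusted p = 0.012 with an estimated correlation) and Emg1 cKO (13 of 21; median 0.46, adjusted p = 3.2e-07; adjusted p = 0.017), and did not pass in Vangl2 Lp/Lp (2 higher, 2 lower; median 0.23, adjusted p = 0.096), where none was lower without wild type replicate 2 or Vangl2 Lp/Lp replicate 3 and 1 without wild type replicate 3 or Vangl2 Lp/Lp replicate 2. Pax1 rose 1.82-fold, 1.86-fold and 1.5-fold. Genes of lateral plate and limb bud mesenchyme were lower in beta-catenin cKO (11 of 20; median -0.43, adjusted p = 3.4e-10, and adjusted p = 0.027 with an estimated correlation), in Emg1 cKO (8; median -0.23, adjusted p = 0.00012; adjusted p = 0.11) and in Vangl2 Lp/Lp (1, Msx1; median -0.20, adjusted p = 0.016; adjusted p = 0.32). Lhx9 fell 2.23-fold in beta-catenin cKO and Hand2 1.98-fold in Emg1 cKO, while Msx1 in Vangl2 Lp/Lp (adjusted p = 0.045) was lost without wild type replicates 2 or 3 or Vangl2 Lp/Lp replicates 1 or 3 (adjusted p up to 0.18), and no gene of the list was lower there with quantile scaling, library totals alone or log2(TPM + 1). The Vangl2 Lp/Lp median was -0.087 without Vangl2 Lp/Lp replicate 1. Nephric duct and intermediate mesoderm genes were higher in beta-catenin cKO (7 of 10; median 0.66, adjusted p = 5.6e-10, and adjusted p = 0.012 with an estimated correlation) and in Emg1 cKO (5, or 3 with quantile scaling; median 0.29, adjusted p = 0.00062; adjusted p = 0.075), and did not pass in Vangl2 Lp/Lp (adjusted p = 0.14). Ret rose 1.85-fold in beta-catenin cKO. Posterior Hox genes were lower in beta-catenin cKO (2 of 16; median -0.25, adjusted p = 0.028, and adjusted p = 0.56 with an estimated correlation), where Hoxa11 (-0.64 ± 0.15, adjusted p = 0.011) was at adjusted p = 0.050 without wild type replicate 3. None was lower without that library, and 1 without wild type replicate 2 or beta-catenin cKO replicates 1 or 3. With quantile scaling, and with log2(TPM + 1), 1 was lower and 1 higher. These genes did not pass in Emg1 cKO (adjusted p = 0.42) or Vangl2 Lp/Lp (adjusted p = 0.73). Trunk Hox genes were higher in beta-catenin cKO (1 of 15, Hoxb6; median 0.16, adjusted p = 0.039, and adjusted p = 0.38 with an estimated correlation) and did not pass in the other mutants (adjusted p 0.91 and 0.16). Hoxb6 (adjusted p = 0.044) was lost without wild type replicates 1 or 3 or any beta-catenin cKO replicate (adjusted p up to 0.17), while 3 trunk Hox genes were higher with library totals alone, 2 with quantile scaling and 5 with log2(TPM + 1).

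Hindgut and definitive endoderm genes were higher in beta-catenin cKO (2 of 13; median 0.34, or 0.144 with quantile scaling, camera adjusted p = 0.039, and adjusted p = 0.38 with an estimated correlation) and did not pass in Emg1 cKO or Vangl2 Lp/Lp (adjusted p 0.40 and 0.80). Foxa1 rose 1.68-fold in beta-catenin cKO (adjusted p = 0.0087, but 0.053 without beta-catenin cKO replicate 3), and Onecut1 1.68-fold in Emg1 cKO. The 2 became 0 without beta-catenin cKO replicate 3 and 1 without wild type replicate 2. Notochord and floor plate genes did not pass (adjusted p 0.22, 0.82 and 0.082), though Ntn1 rose 1.45-fold, 1.44-fold and 1.35-fold. Yolk sac endoderm genes did not pass (adjusted p 0.62, 0.45 and 0.082). Afp was called in Vangl2 Lp/Lp (4.96 ± 1.35, adjusted p = 0.033) on 108 TPM in replicate 1 alone, against 2.98 and 1.44 TPM in replicates 2 and 3, and was lost without that library or wild type replicates 1, 2 or 3 (adjusted p up to 0.61). Of 7 yolk sac genes 1 was higher in Vangl2 Lp/Lp, 2 without Vangl2 Lp/Lp replicate 2, 4 without Vangl2 Lp/Lp replicate 3 and none without any 1 of the other libraries of the comparison. Erythroid genes were lower in all 3 mutants (11, 13 and 3 of 15, with 1 higher in each; medians -0.53, -0.60 and -0.16, adjusted p 3.5e-09, 1.7e-09 and 0.0090), none with an estimated correlation (adjusted p 0.19, 0.18 and 0.55). None was higher without wild type replicates 1 or 2 or replicates 1 or 2 of the mutant, nor with quantile scaling in Emg1 cKO and Vangl2 Lp/Lp. Hbb-bh1 fell 2.49-fold in Emg1 cKO and Alas2 1.47-fold in Vangl2 Lp/Lp. The 13 of Emg1 cKO became 8 without Emg1 cKO replicate 3, and the 3 of Vangl2 Lp/Lp became 1 without wild type replicate 3 or Vangl2 Lp/Lp replicate 3. With quantile scaling 7, 8 and 1 were lower (medians -0.39, -0.39 and -0.072), and with log2(TPM + 1) 7 in beta-catenin cKO and 1 in Vangl2 Lp/Lp. The Vangl2 Lp/Lp median was -0.27 and -0.072 without Vangl2 Lp/Lp replicates 1 and 3. Endothelial genes were lower in Emg1 cKO (5 of 15; median -0.15, adjusted p = 0.032, and adjusted p = 0.40 with an estimated correlation) and Vangl2 Lp/Lp (3; median -0.14, adjusted p = 0.0018; adjusted p = 0.28), and did not pass in beta-catenin cKO (adjusted p = 0.79). Without any 1 of the 6 libraries of the comparison, 1 to 3 genes were lower in Emg1 cKO; there were 1 with library totals alone, 2 with quantile scaling and 0 with log2(TPM + 1). Tek (adjusted p = 0.012) was lost without wild type replicate 1 (adjusted p = 0.053), and none was lower in Vangl2 Lp/Lp without Vangl2 Lp/Lp replicate 1 or with log2(TPM + 1). The Vangl2 Lp/Lp median was -0.089 without wild type replicate 3. Kdr in Vangl2 Lp/Lp (adjusted p = 0.0098) was lost without Vangl2 Lp/Lp replicate 1 (adjusted p = 0.053). Macrophage genes were higher as a list in beta-catenin cKO, with none of 12 called (median 0.35, or 0.213 with quantile scaling, adjusted p = 0.034, and adjusted p = 0.38 with an estimated correlation). The list did not pass in Emg1 cKO (2 higher; adjusted p = 0.17) or Vangl2 Lp/Lp (none called; adjusted p = 0.16), nor between beta-catenin cKO and Emg1 cKO (median 0.04, adjusted p = 0.55). With log2(TPM + 1) 1 was higher in beta-catenin cKO and 1 in Vangl2 Lp/Lp. The 2 of Emg1 cKO became 1 with quantile scaling and without wild type replicates 1 or 2 or any Emg1 cKO replicate. Mrc1 rose 1.57-fold in Emg1 cKO (adjusted p = 0.015, but 0.051 without wild type replicate 1). Primordial germ cell genes did not pass (adjusted p 0.14, 0.17 and 0.32). Pou5f1 in Vangl2 Lp/Lp (adjusted p = 0.026) was lost without wild type replicates 2 or 3 or Vangl2 Lp/Lp replicate 2 (adjusted p up to 0.096). X inactivation and Y-linked genes did not pass (adjusted p 0.62, 0.82 and 0.74).

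Lists of growth, cell cycle and stress are given in the same order of mutants. Cytosolic ribosomal protein genes were lower (15, 45 and 10 of 79, with 2, 1 and 1 higher; medians -0.18, -0.25 and -0.17, or 0.01, -0.04 and -0.03 with quantile scaling; camera adjusted p 5.3e-08, 1.3e-12 and 5.6e-11; adjusted p 0.46, 0.48 and 0.55 with an estimated correlation). With quantile scaling only 1, 2 and 1 were lower and 5, 3 and 0 higher. The lower genes numbered 6, 25 and 5 with library totals alone and 2, 13 and 3 with log2(TPM + 1). The counts moved with single libraries. They were 59, 70 and 51 without wild type replicate 1 and 5, 25 and 5 without wild type replicate 3, where the medians were -0.055, -0.13 and -0.052, and the Vangl2 Lp/Lp median was -0.255 without wild type replicate 1. They were 4, 7 and 3 without beta-catenin cKO replicates 1, 2 and 3, then 28 and 27 without Emg1 cKO replicates 1 and 2, and 1, 5 and 4 without Vangl2 Lp/Lp replicates 1, 2 and 3. Rpsa fell 1.31-fold in Emg1 cKO and Rpl4 1.19-fold in Vangl2 Lp/Lp, while Rpl26 rose 2.02-fold in beta-catenin cKO. S phase genes were lower (10, 13 and 4 of 20; medians -0.18, -0.22 and -0.15, adjusted p 1.3e-06, 1.5e-08 and 5.9e-06; adjusted p 0.19, 0.11 and 0.28 with an estimated correlation). With quantile scaling 2, 6 and 0 were lower (medians -0.08, -0.13 and -0.07), with log2(TPM + 1) 1, 5 and 0, and with library totals alone 2 in Vangl2 Lp/Lp. Fen1 fell 1.21-fold in beta-catenin cKO and Cdc6 1.34-fold in Emg1 cKO. The 10 became 6 without wild type replicate 3 and 5 and 4 without beta-catenin cKO replicates 1 and 3. In Vangl2 Lp/Lp no S phase gene was called lower without wild type replicates 2 or 3 or Vangl2 Lp/Lp replicates 1 or 3, Ccne1 among those lost (adjusted p 0.024, up to 0.11). G2/M genes were lower (4, 8 and 0 of 22; medians -0.09, -0.11 and -0.09, adjusted p 0.028, 0.020 and 0.0090; adjusted p 0.46, 0.53 and 0.55 with an estimated correlation). With log2(TPM + 1) the medians of beta-catenin cKO and Emg1 cKO were 0.03 and 0.01, no gene was lower and 2 were higher in Emg1 cKO. The 4 and 8 became 0 and 1 with quantile scaling and 1 and 3 with library totals alone. The 4 became 1, 1 and 0 without wild type replicate 3 and beta-catenin cKO replicates 1 and 3. Cdk1 (adjusted p = 0.014) was lost without wild type replicate 3 or beta-catenin cKO replicate 3 (adjusted p up to 0.073). The 8 became 5, 5, 3 and 4 without wild type replicates 2 and 3 and Emg1 cKO replicates 2 and 3, and the Emg1 cKO median was -0.066 without the last. Birc5 fell 1.18-fold. Hypoxia and glycolysis genes were lower in Emg1 cKO (11 of 24 and 1 higher, or 7 and 3 with log2(TPM + 1); median -0.23, adjusted p = 2.9e-06, and adjusted p = 0.074 with an estimated correlation) and Vangl2 Lp/Lp (7; median -0.14, adjusted p = 2.3e-05; adjusted p = 0.20) and did not pass in beta-catenin cKO (adjusted p = 0.086), where Mif fell 1.64-fold. The 7 became 4 without Vangl2 Lp/Lp replicate 3 and 3 with quantile scaling. Genes of the unfolded protein and integrated stress response were lower in beta-catenin cKO (7 of 22, with 1 higher; median -0.21, or -0.125 with quantile scaling, adjusted p = 0.00011, and adjusted p = 0.19 with an estimated correlation) and Emg1 cKO (13, with 1 higher; median -0.38, adjusted p = 2.5e-08; adjusted p = 0.093), and did not pass in Vangl2 Lp/Lp (adjusted p = 0.080). Asns fell 1.63-fold, 1.61-fold and 1.36-fold. The 7 became 3 or 4 without wild type replicates 2 or 3 or any beta-catenin cKO replicate, 3 with quantile scaling and 1 with log2(TPM + 1). None was higher without beta-catenin cKO replicate 2. In Emg1 cKO 2 were higher without Emg1 cKO replicate 1, with library totals alone or with log2(TPM + 1). Immediate early genes did not pass (adjusted p 0.75, 0.42 and 0.73). Jun was called in beta-catenin cKO (adjusted p = 0.015; 0.074 without beta-catenin cKO replicate 3) and Vangl2 Lp/Lp (adjusted p = 0.025; up to 0.081 without wild type replicates 2 or 3 or Vangl2 Lp/Lp replicates 1 or 3), and Myc fell 1.31-fold in Emg1 cKO.

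Among lists of signalling, SHH targets were higher in beta-catenin cKO (5 of 12; median 0.30, camera adjusted p = 0.00050, and adjusted p = 0.19 with an estimated correlation), with Foxf2 up 1.69-fold, and did not pass in Emg1 cKO or Vangl2 Lp/Lp (adjusted p 0.056 and 0.16), though Boc rose 1.39-fold and 1.34-fold. FGF targets were lower in beta-catenin cKO (6 of 13, with 1 higher; median -0.18, adjusted p = 0.048, and adjusted p = 0.38 with an estimated correlation), with Spry4 down 1.55-fold. The 6 became 3, 3 and 2 without wild type replicate 2 and beta-catenin cKO replicates 1 and 3, and 2 with log2(TPM + 1). With median ratio or quantile scaling, library totals alone or log2(TPM + 1), and without wild type replicate 2, 2 were higher. The median was -0.095 without wild type replicate 2 and -0.10 without beta-catenin cKO replicate 3. FGF targets did not pass in Emg1 cKO or Vangl2 Lp/Lp (adjusted p 0.55 and 0.14), where Dusp4 rose 1.41-fold and 1.36-fold. Notch targets were higher in Vangl2 Lp/Lp (3 of 12; median 0.24, adjusted p = 0.0057, and adjusted p = 0.42 with an estimated correlation) and did not pass in the other mutants (adjusted p 0.64 and 0.17). Dtx4 rose 1.27-fold, 1.44-fold and 1.49-fold, and the 3 became 1 without wild type replicate 3 or Vangl2 Lp/Lp replicate 3 or with quantile scaling. BMP targets did not pass (adjusted p 0.10, 0.10 and 0.14), with Id4 up 2.42-fold in Emg1 cKO and 1.93-fold in Vangl2 Lp/Lp. Retinoic acid targets did not pass (adjusted p 0.074, 0.33 and 0.24), with Crabp2 down 1.46-fold in beta-catenin cKO and Aldh1a2 down 1.34-fold in Vangl2 Lp/Lp.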

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

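Added after the data were seen were the tests with DESeq2 and library totals alone, log2(TPM + 1) as an alternative (it had been planned for TPM alone), list tests and shared genes without each library, and shared genes with no filter, quantile scaling or 2 groups. Of 3930 checks on called named genes 3690 kept the call and 240 lost it, none with a reversed direction; 146 of 199 named calls stood under every alternative run. Of 473 checks on named genes not called, 393 stayed so, 68 gained a call and 12 changed direction. Of 330 checks on core lists 296 were the same, 24 lost the call, 6 gained it and 4 changed direction. For the changes given here the cause was not tested, unless named.

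Counts of genes called moved as follows. Requiring a fold of at least 2, which by construction lowers counts, left 477, 553 and 301 genes in beta-catenin cKO, Emg1 cKO and Vangl2 Lp/Lp against wild type, 161 between beta-catenin cKO and Emg1 cKO, 207 between beta-catenin cKO and Vangl2 Lp/Lp and 97 between Emg1 cKO and Vangl2 Lp/Lp. With no filter, Vangl2 Lp/Lp had 2624 genes, the pairs of mutants in the same order 1308, 1339 and 1244, and the shared genes came to 1366. Fits of only the 2 groups gave 737 for Vangl2 Lp/Lp, 294 for Emg1 cKO against Vangl2 Lp/Lp and 443 shared. Quantile scaling gave 1641 for beta-catenin cKO, 693 for Vangl2 Lp/Lp and 360 shared. Library weights gave 3916 for beta-catenin cKO and 1663, 1164 and 1438 between mutants. DESeq2 gave 990 for beta-catenin cKO against Emg1 cKO and 940 for Emg1 cKO against Vangl2 Lp/Lp, where log2(TPM + 0.1) gave 312. Unadjusted p under 0.05 gave 2346 shared genes. Leaving out single libraries gave 1436 to 2643 in beta-catenin cKO, 719 to 1444 in Vangl2 Lp/Lp, 231 to 521, 371 to 576 and 186 to 666 between mutants, and 478 to 929 shared.

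Of the targeted genes, Ctnnb1 in beta-catenin cKO was at -0.11 and called with library weights, and changed sign to 0.022 with log2(TPM + 0.1), 0.022 with log2(TPM + 1) and 0.081 with quantile scaling. In Emg1 cKO Ctnnb1 was at 0.019 with a filter of 5 TPM, 0.044 with library totals, 0.11 with log2(TPM + 0.1), 0.11 with log2(TPM + 1), 0.19 with quantile scaling, 0.00054 with 2 groups and -0.029 to 0.0079 without single libraries. Vangl2 gained a call in beta-catenin cKO at 0.17 with a filter of 5 TPM, 0.19 with library totals, 0.26 with log2(TPM + 0.1), 0.26 with log2(TPM + 1) and 0.21 with quantile scaling. In Vangl2 Lp/Lp it did so at 0.18 with a filter of 5 TPM, 0.20 with library totals, 0.25 with log2(TPM + 0.1), 0.25 with log2(TPM + 1) and 0.17 with DESeq2. Emg1 in Vangl2 Lp/Lp gained a call at -0.24 with DESeq2 and -0.26 with no filter, and in beta-catenin cKO at -0.21 with no filter. Without single libraries it lay at -0.30 to -0.13 and -0.26 to -0.091. Eif2s3y in Emg1 cKO lay at -0.59 to 0.015 without single libraries.

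With an estimated correlation these lists lost their call, at unchanged medians. In beta-catenin cKO they were WNT/beta-catenin targets (-0.42), progenitors (0.30), neurons (0.57), tail bud (-0.28), planar cell polarity (0.15) and ribosome biogenesis (-0.21). In Emg1 cKO they were WNT/beta-catenin targets (-0.30), epidermal genes (-0.47), progenitors (0.38), neurons (0.73), tail bud (-0.24), planar cell polarity (0.13) and ribosome biogenesis (-0.26). In Vangl2 Lp/Lp they were surface ectoderm (-0.25), border and crest (0.20), progenitors (0.42), neurons (0.55), planar cell polarity (0.16) and ribosome biogenesis (-0.17). With fry the tail bud list was not called in beta-catenin cKO (-0.28, adjusted p = 0.075) or Emg1 cKO (-0.24, adjusted p = 0.11), and p53 targets were called in Emg1 cKO (0.086, adjusted p = 0.045). With log2(TPM + 0.1) the epidermal list was called in beta-catenin cKO (-0.12, adjusted p = 0.014), and the direction of the p53 list, which was not called, turned to higher in beta-catenin cKO (median 0.12) and Vangl2 Lp/Lp (median 0.085). With a replicate block the tail bud list was called in Vangl2 Lp/Lp (0.22, adjusted p = 0.043). Medians without single libraries were 0.093 to 0.16 and 0.072 to 0.17 for planar cell polarity in beta-catenin cKO and Emg1 cKO, and -0.40 to -0.12 for epidermal genes in beta-catenin cKO. They were -0.15 to -0.0017 for border genes in Emg1 cKO, and -0.038 to 0.10 for WNT/beta-catenin targets and 0.15 to 0.32 for the tail bud in Vangl2 Lp/Lp. The direction of the border list turned without Emg1 cKO replicate 1, and that of the WNT/beta-catenin targets without Vangl2 Lp/Lp replicate 1; neither list was called.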

Other observations

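Among the tests in this part, the comparison of posterior with trunk Hox genes and the share of genes called at 4-fold or more that lie near another, with and without the largest cluster, were chosen after the result was seen. So was Serpinf2, and so was the choice of which genes to name among those listed beforehand.

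Changes common to the mutants were weighed first. Simulated were 20 sets of unchanged groups that shared their controls as here. In none of them was any gene called the same way in all 3 mutants, against the 880 observed. Noise that is independent between genes thus does not give this number through shared controls. A shift of many genes common to the 3 wild-type libraries was not simulated, so such a shift stays open. Removing trends with gene length and GC content left 1.01, 0.985 and 1.05 times the neuron median in beta-catenin cKO, Emg1 cKO and Vangl2 Lp/Lp, which argues against such a bias as its whole cause. A tissue piece taken at another axial level in every mutant would move posterior against trunk Hox genes the same way, but the difference of medians was -0.41, 0.075 and -0.17. This bears only on a shift common to all 3 mutants. In beta-catenin cKO posterior Hox genes were lower and trunk Hox genes higher as lists, so another axial level stays open there. Younger wild-type embryos may still have contributed: the median of 8 genes that fall with stage was -0.13, -0.0996 and -0.13, with 3, 3 and 1 of them called lower, Lin28a in Emg1 cKO among them (-1.15 ± 0.12, adjusted p = 2.5e-05), too close to the bound of -0.1 to decide. All 3 wild-type libraries had fewer genes above 1 TPM (16143 to 16364) than any mutant library (16794 to 17115). Their TMM scaling factors were also lower, at 0.973 to 0.979 against 0.995 to 1.015. Whether a batch or another difference in library make-up lies behind this was not tested. Litter, strain and batch are not given, so a difference in them between wild type and mutants could not be told apart from genotype. An effect of the mutations therefore stays a hypothesis. Whether the shares of cell types differed between genotypes was not tested.

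Heart muscle transcripts stood out in Vangl2 Lp/Lp replicate 1. Myl7, Myh6 and Myh7 were seen first. Of 14 other heart genes, listed before their values were seen, 13 (92.9%) had their highest TPM there, with Sln the exception (0.144 against 1.71), and 6 of the 7 that passed the filter. Myl7 lay at 220 TPM against at most 8.68 elsewhere, Myh7 at 102 against 4.83, Myh6 at 95.5 against 1.96, Myl2 at 76.9 against 0.327, Nppa at 76.0 against 0.430 and Tnnt2 at 28.7 against 6.12. A candidate explanation is that this pool held some heart tissue. Afp at 108 TPM against at most 19.1, and Serpinf2 at 14.8 TPM, were highest in the same library and are not heart genes, and biological explanations were not tested beyond heart tissue.

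Alleles of another strain near the mutated genes, or at other loci, were weighed last. Calls in Vangl2 Lp/Lp were more frequent within 10 Mb of Vangl2 (26 of 176 genes, 14.8%) than elsewhere (8.74%), with an odds ratio of 1.81 (95% interval 1.14 to 2.77, Fisher's exact p = 0.010, 0.030 adjusted over 3 loci), and 2.29 and 1.84 within 5 and 20 Mb. Fisher's test takes genes as independent, which neighbouring paralogs such as Ifi204 and Ifi207 may not be, so the interval may be too narrow. Both lie in this window and were also called higher in beta-catenin cKO, and Ifi204 in Emg1 cKO as well. Both rose most in Vangl2 Lp/Lp (4558 and 346 reads, elsewhere at most 787 and 113), so linked alleles may still contribute. Near Ctnnb1 and Emg1 the odds ratios were 1.37 and 1.1 (Fisher's exact p = 0.22 and 0.53), which leaves it open. Of 30 genes called at 4-fold or more in all 3 mutants, 15 (50%) lay within 2 Mb of another, against a median of 6.67% and a 95th percentile of 20% in 2000 draws, but 13 of them formed a single cluster on chromosome 2 (175372436 to 176927809) of paralogs that can share reads, and outside it 2 of 17 (11.8%) did, against a 95th percentile of 11.8%. All 13 were higher in all 3 mutants. The largest of them, named after their values were seen, were 2210418O10Rik (log2 fold changes 8.36, 8.53 and 7.90) and Gm14296 (7.97, 7.95 and 7.43). The order is beta-catenin cKO, Emg1 cKO and Vangl2 Lp/Lp. The check outside the cluster could not cover alleles of another strain at this single locus, so these stay open.

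The 6 libraries of a comparison make 10 splits into groups of 3, too few for a share under 0.05. In fits of only the 2 groups, 1 of the 10 splits, the real one, gave as many genes in each comparison. The real splits gave 2393, 2883 and 737 genes for beta-catenin cKO, Emg1 cKO and Vangl2 Lp/Lp against wild type, and the highest of the others 2, 0 and 1 with edgeR. They gave 802, 719 and 294 for beta-catenin cKO against Emg1 cKO, beta-catenin cKO against Vangl2 Lp/Lp and Emg1 cKO against Vangl2 Lp/Lp, and the highest of the others 1, 2 and 0.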
